A study of Mus musculus with 4 samples.

How the data were processed

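RNA was measured in 4 libraries of sorted pancreatic β-cells from mice given doxycycline for 10 days, 2 labelled Bmal1 KO and 2 labelled Bmal1 heterozygous, as the sample titles and genotypes give them. Per the labels' protocols, total RNA was isolated with an RNeasy Plus Micro kit and made into libraries with a SMART-Seq v4 low-input kit, which does not mark strand. The submitters' processing notes name STAR, edgeR and mm10, with no version and no role for either tool; the counting tool, its strand setting and the gene annotation are not given in the sources used here. The authors deposited a table of whole-number read counts per gene symbol, with no normalization, and that table was used for all main tests. The authors also deposited a scaled table, treated here as a signal, whose values equal the counts times 1 constant per library on 14649 of the genes; whole reads were recovered from 99.97% to 99.99% of the deposited values at a tolerance of 0.01.

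The count table has 23420 genes, of which 5472 are 0 in all libraries. Totals per library were 32819600, 31056100, 38020500 and 34776900 counts. A count of 3, used as the floor where a library has 0, equals 0.0775 to 0.0937 CPM. Reads carry no molecular identifiers, so floors and intervals cover counting error only. Among its gene names 2 are duplicates and 27 were turned into dates, of which 23 were tested and 0 passed; they are not named. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 64.2 for the KO label and 43.1 for the heterozygous label, so no library was counted as a copy of another. Pearson correlations of log2 CPM (prior count 3) across genes were 0.945 within the KO label, 0.971 within the heterozygous label and 0.927 to 0.937 between labels; genes are not independent replicates.

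Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 with group as the only term, on all 4 libraries. The test is 2-sided and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The fit had 2 residual and 5.12 prior degrees of freedom and a biological coefficient of variation of 0.297. Before the data were examined, 31 gene lists, the rule for named genes and the alternatives were fixed. The lists were textbook sets: clock genes driven through E-boxes or repressed by REV-ERB, β-cell identity, secretory granule, exocytosis, mitosis, DNA replication, cell cycle entry, dedifferentiation, ER stress, antioxidant, p53, interferon, NF-κB, immediate early, glycolysis, respiratory chain, mitochondrially encoded, ribosomal and cholesterol genes, markers of α, δ, PP and ε, acinar, duct, endothelial, stromal, immune, erythroid and neuronal cells, and sex-linked genes. Lists of at least 5 measured genes, 29 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list moves 1 way and does not compare it with other genes.

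By the rule, the text names Arntl, for each direction the 10 genes with the smallest adjusted p and the 5 with the largest fold at a mean of 10 CPM or more, provided the groups did not overlap, up to 5 genes past the threshold per list or else the 3 with the smallest p, and 17 β-cell, hormone and clock genes whatever their test. It gave 116 genes, 78 of them past the threshold, and a few of these are not reported here. Unnamed gene models ending in Rik or starting with Gm, 11 of those past the threshold, were counted and not named. Coordinates are from GENCODE release M21 (GRCm38), where 93.6% of tested symbols were found. Counting without strand cannot separate overlapping genes: exons of 12 named genes overlap another protein-coding gene, among them Nr1d1, Dbp, Junb, Pfkp, Pdia6, Col4a1, Fancd2 and Cox6a2, and their values are uncertain to that extent. Ins1 and Ins2, the ribosomal protein genes and other genes with near-identical copies are uncertain too, since the treatment of reads with several matches is not given in the sources used here.

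The procedure was tested on simulated data, with 200 of 14649 genes changed in each of 5 sets. Counts were drawn from the observed means, dispersions and library sizes, each gene independently of the others. On data drawn the same way camera with the preset correlation called 2 of 145 unchanged lists. That does not show its error rate for lists whose genes vary together. Alternatives were other scalings (RLE, upper quartile, library sizes only, the top 20 genes taken out), no filter or a mean of 5 CPM, DESeq2 1.42.0, limma-voom, limma-trend on the deposited scaled values, a replicate block, leaving out each library, a test against a fold of 1.5 and a threshold of 0.1. Recovered reads, counts per list and a fit without markers of other cells were added after seeing the data, as were Reactome sets, taken from the fgsea 1.28.0 package and matched through Entrez identifiers for 99.4% of genes. Where a library was left out, the lone library of its group was assumed to vary like the other group. With 2 libraries per group the samples can be split in 3 ways only, so no permutation test was made.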

Results

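RNA sequencing of sorted mouse pancreatic β-cells was used to compare animals labelled Bmal1 knockout (KO) with animals labelled Bmal1 heterozygous. Both groups carried DTA, and per the labels the β-cells measured are those left after an ablation induced by 10 days of doxycycline. Bmal1 is the common name of Arntl, which encodes a transcription factor that pairs with CLOCK to drive the circadian clock. Each group had 2 libraries, made from low-input total RNA with a SMART-Seq v4 kit. The deposited counts summed to 32819600 and 31056100 in the libraries labelled KO and to 38020500 and 34776900 in those labelled heterozygous. Ins2 alone took 15.5% to 19.5% of the counts of a library, and the 20 most abundant genes took 30.98% to 35.1%. Nothing in the labels says whether the 2 libraries of a group came from separate animals, so every p-value measures the spread between these libraries, which may be technical. Sex-linked RNA differed between KO replicates 1 and 2 (Xist 8.68 and 38.8, Ddx3y 89.1 and 23.8, Eif2s3y 136 and 32.3 CPM). This argues against the same sample prepared again for the KO label, while the heterozygous label stays open. Each library held both Xist and Y-linked RNA, so a library may hold RNA of both sexes and need not stand for 1 animal. Values below are TMM-scaled CPM, as mean ± SD with n = 2 per group, and p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless named otherwise.

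RNA of the targeted gene was higher in the libraries labelled KO. Arntl (chromosome 7, 113207465 to 113314126, GRCm38, plus strand) was at 70.7 ± 7.22 CPM in the libraries labelled KO and at 19.0 ± 5.69 CPM in those labelled heterozygous, a log2 fold change of 1.89 (SE 0.24, edgeR adjusted p = 0.0175). The counts were 2490 and 2101 in the libraries labelled KO and 892 and 495 in those labelled heterozygous, so Arntl was higher in 2 of 2 libraries. Counts cover the gene as a whole, and nothing in them shows whether a deleted part is missing, so they neither bear out nor exclude a knockout. For that reason the groups are called by their labels throughout, and each direction below is that of the libraries labelled KO relative to those labelled heterozygous. Without heterozygous replicate 2 the log2 fold change was 1.61 with an adjusted p of 0.0724.

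Other clock genes split into genes that rose and genes that fell in the libraries labelled KO. Npas2, whose protein can stand in for CLOCK, rose from 6.54 ± 3.46 to 57.9 ± 8.21 CPM (log2 fold change 3.14, SE 0.37, edgeR adjusted p = 0.0145). Nr1d2, which encodes the repressor REV-ERBβ, fell from 58.0 ± 9.02 to 7.46 ± 3.10 CPM (log2 fold change -2.96, SE 0.32, adjusted p = 0.0129), and Per3 fell from 21.1 ± 6.13 to 4.47 ± 0.138 CPM (-2.24, SE 0.31, adjusted p = 0.0195). Of 17 genes listed as driven through E-boxes, the DNA element BMAL1 and CLOCK bind, 5 rose (among them Hlf and Cry1, and Bhlhe40 and Cry2, the last pair named after their values were seen), 2 fell and 10 did not pass. Adjusted over the list alone, 6 were higher and 4 lower. Cry1 rose from 48.3 ± 5.08 to 171 ± 32.7 CPM and Hlf from 3.82 ± 1.17 to 19.0 ± 2.84 CPM. Nr1d1, which encodes REV-ERBα, was at 17.2 ± 3.75 against 59.8 ± 40.5 CPM and did not pass (log2 fold change -1.80, adjusted p = 0.102). Dbp (-0.35), Per1 (0.50) and Per2 (0.44) did not pass either. Of 5 measured genes listed as repressed by REV-ERB, Npas2 and Nfil3 rose, the latter from 42.0 ± 4.52 to 135 ± 22.8 CPM, and 3 did not pass, with the same counts adjusted over the list alone. The E-box list as a set was higher by camera with a preset correlation (adjusted p = 0.0284; adjusted p = 0.421 with an estimated correlation), and so was the REV-ERB list (adjusted p = 0.000988; adjusted p = 0.250 with an estimated correlation). The E-box call was lost without KO replicate 2 (adjusted p = 0.0888) and without heterozygous replicate 2 (adjusted p = 0.420), where 1 member passed as higher. By limma-voom and by limma-trend on the deposited values neither list passed (E-box adjusted p = 0.155 and 0.345, REV-ERB adjusted p = 0.0646 and 0.143). The E-box median of 0.44 was 0.0014 without KO replicate 2 and 0.17 without heterozygous replicate 1. The REV-ERB median of 0.75 was 0.087 and 0.14 in these and 1.24 and 1.57 without KO replicate 1 and heterozygous replicate 2. Stromal (median 2.68), acinar (2.16) and immune (1.17) markers and sex-linked levels, given below, differed in the same libraries.

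**Figure D1:**
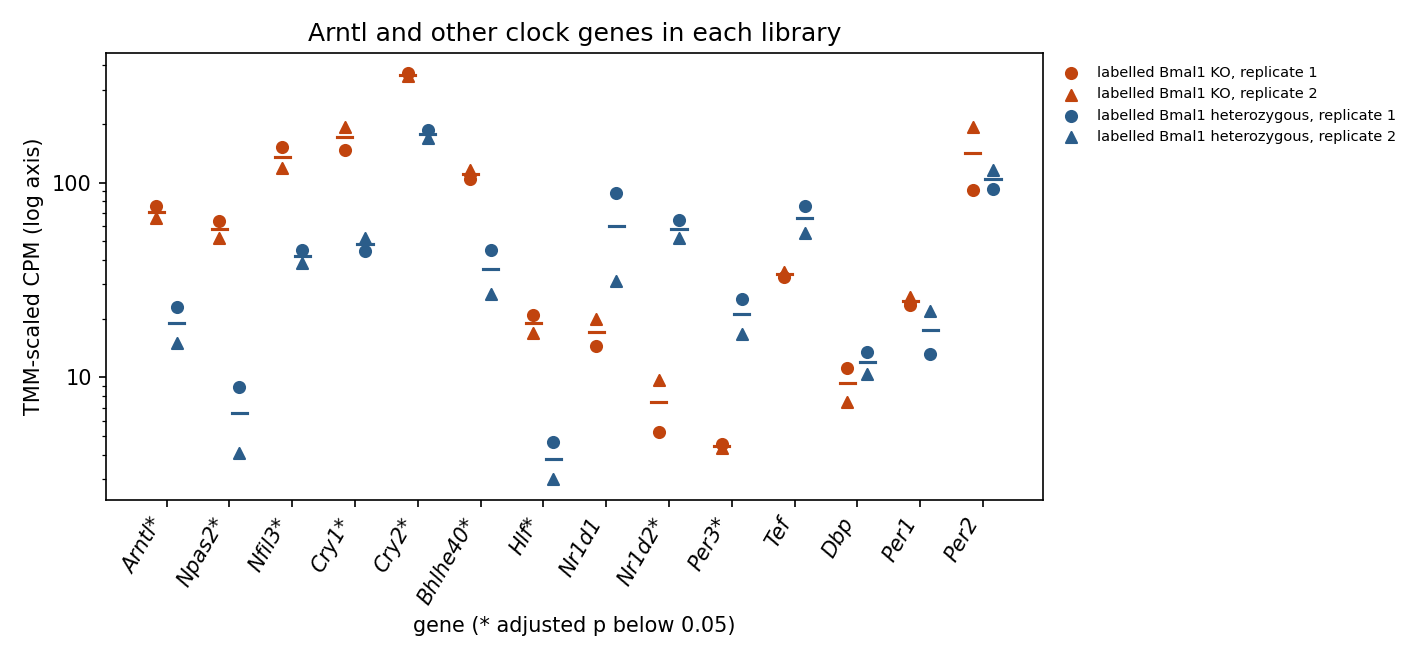
Level of Arntl and 13 other clock genes in each of the 4 libraries, in TMM-scaled CPM on a log axis; orange marks libraries labelled Bmal1 KO, blue those labelled heterozygous, and short lines are group means. Arntl lies at 65.6 and 75.8 CPM in the libraries labelled KO and at 14.98 and 23.03 CPM in the others, and Nr1d2 and Per3 lie the other way.

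Over all 14649 genes tested, 176 were higher and 196 lower in the libraries labelled KO, 2.54% of the genes in all. Nyap2 (chromosome 1, 81076950 to 81341764) was at 27.5 ± 4.20 against 0.744 ± 0.153 CPM, Dlc1 (chromosome 8, 36567751 to 36953143) at 28.9 ± 9.47 against 0.701 ± 0.178 CPM, and S100a6, a calcium-binding protein gene, at 127 ± 65.5 against 2.34 ± 1.04 CPM. Prkg2, a cGMP-dependent kinase gene, had 516 and 331 counts against 3 and 4, a ratio of 134 with a 95% counting interval of 64.7 to 334 (exact binomial). Among the other genes that rose most by the naming rule were Asb11 (log2 fold change 2.89), Slc41a3 (4.25), Dcdc2a (2.99), Sgpl1 (1.62), Ppp1r3c (5.12) and Smo (4.92), the last a receptor of hedgehog signalling. In the other direction, Ncaph (chromosome 2, 127103809 to 127133954), a condensin subunit gene, was at 5.68 ± 0.537 against 35.1 ± 0.324 CPM, F13a1, a clotting factor subunit gene, at 5.74 ± 0.669 against 34.7 ± 0.852 CPM, and C1qtnf1 at 41.6 ± 0.286 against 144 ± 13.3 CPM. Tcf19 (log2 fold change -2.38), Sapcd2 (-2.46), Cox6a2 (-2.26), Fancd2 (-3.88), Casc5 (-2.98), Ndc80 (-2.54) and Troap (-3.05) also fell. The libraries of the groups did not overlap for any of the 372 genes past the threshold. Chance gives 33.3% of genes, and 49.0% of all tested genes showed no overlap. The 372 were picked by a test on these same libraries, so their lack of overlap is no further support. Without heterozygous replicate 2, 17 genes were higher and 8 lower, and without heterozygous replicate 1, 129 and 94. Without KO replicate 1 the counts were 296 and 267, and without KO replicate 2 they were 404 and 422. In simulated data the same test found 32.2% of 2-fold and 74.5% of 4-fold changes, and 13.5% of its calls were unchanged genes, so more of the calls can be false than the threshold of 0.05 states.

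Genes of cell division were lower in the libraries labelled KO. All 39 mitosis genes measured had a lower level, with a median log2 fold change of -2.37, and 28 fell, 11 did not pass and 0 rose. All 39 were lower when adjusted over the list alone. Mki67, a marker of cycling cells, fell from 127 ± 40.7 to 26.0 ± 8.14 CPM (log2 fold change -2.29, SE 0.30, edgeR adjusted p = 0.0175), Aurkb, a mitotic kinase gene, from 27.6 ± 3.63 to 2.65 ± 1.59 CPM and Cenpf from 63.6 ± 9.63 to 9.23 ± 6.68 CPM. Sgol1 (-2.81), Kif23 (-2.72) and Nuf2 (-2.70), which act at kinetochores or in cytokinesis, fell too. Summed over the list, the libraries labelled KO held 316 and 536 CPM and those labelled heterozygous 1659 and 2040 CPM. Of 40 DNA replication genes, 18 fell and 22 did not pass, 32 were lower adjusted over the list alone, and the median was -1.28. Cdc6 (-2.56), Uhrf1 (-2.56), Dtl (-2.40), Mcm10 (-2.09) and Chaf1b (-2.07) were among those that fell. Of 24 genes of cell cycle entry and its inhibitors, Cdkn2c (-1.87) and Cdkn2d (-1.74), both of which encode inhibitors of CDK4 and CDK6, fell and 22 did not pass; adjusted over the list alone, 5 were lower and 2 higher. The stromal list was higher by camera in the same libraries (adjusted p = 1.64e-19; adjusted p = 0.250 with an estimated correlation), summed immune markers were high in KO replicate 2 alone, and Xist and Y-linked levels differed between libraries. By camera with a preset correlation the mitosis list was lower (adjusted p = 3.77e-77), as were the replication list (8.10e-34) and the entry list (0.00202), with adjusted p = 0.250, adjusted p = 0.135 and adjusted p = 0.320 with an estimated correlation, respectively. By limma's fry the replication list alone passed (adjusted p = 0.0299). Without heterozygous replicate 2, 0 mitosis genes and 0 replication genes passed in edgeR's test while the list medians were -2.20 and -1.25, and without heterozygous replicate 1, 4 replication genes passed.

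**Figure D2:**
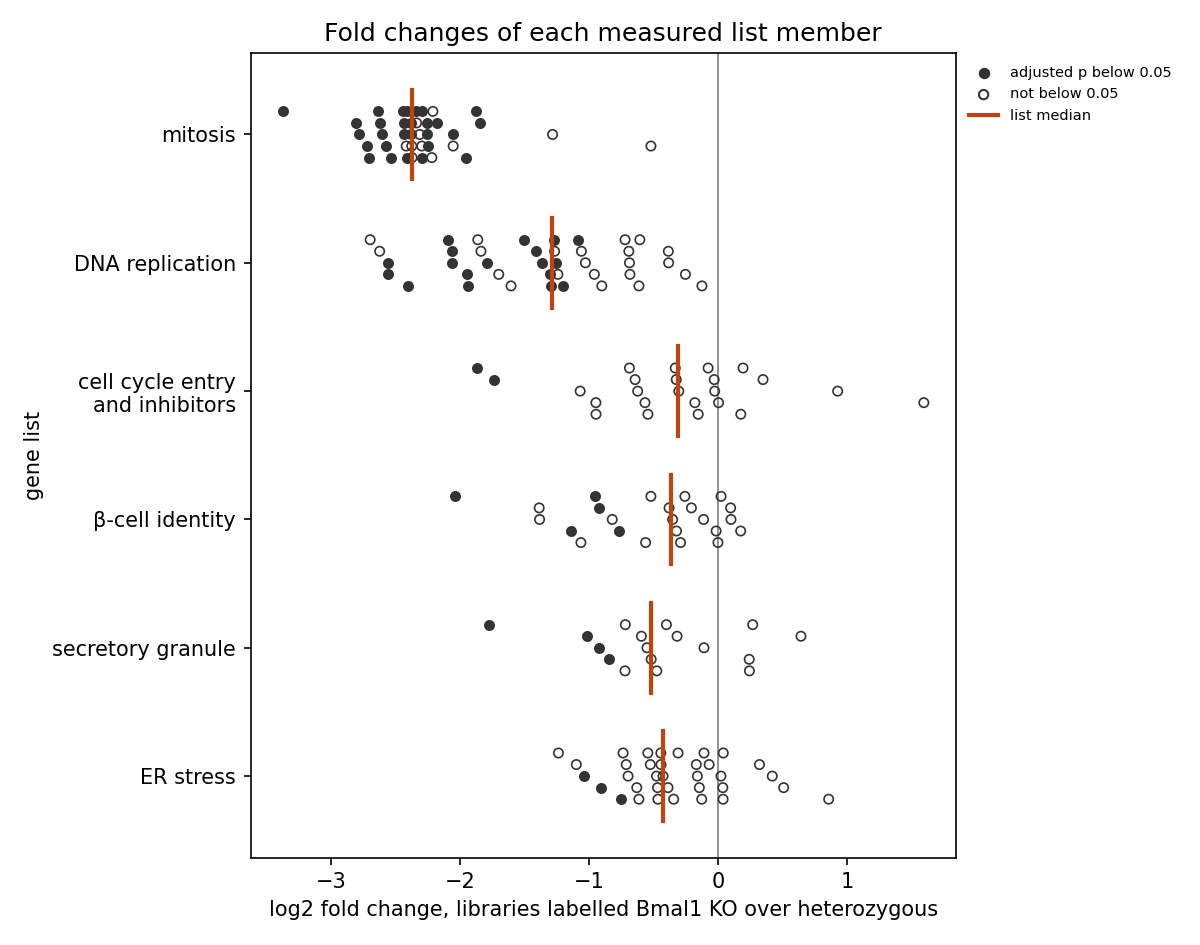
Log2 fold change (libraries labelled Bmal1 KO over heterozygous) of every measured member of 6 gene lists; each point is a gene, filled where edgeR's adjusted p was below 0.05, and the orange line is the list median. All 39 mitosis genes lie below 0, with a median of -2.37, while the β-cell identity list has a median of -0.37.

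Several genes of mature β-cells fell in the libraries labelled KO, and neither insulin gene passed. Ins2 was at 181699 ± 18173.7 CPM in the libraries labelled KO and 169512 ± 25158.9 CPM in those labelled heterozygous (log2 fold change 0.10, SE 0.14), and Ins1 at 26724.4 ± 11.9 against 34775.9 ± 6331.47 CPM (-0.38, SE 0.15, edgeR adjusted p = 0.254). For Ins1 both libraries labelled KO lay below both labelled heterozygous, so a lower level is not excluded. Ucn3, a hormone gene of mature β-cells, fell from 292 ± 31.4 to 71.0 ± 25.6 CPM (-2.04, SE 0.25, edgeR adjusted p = 0.0160), and Glp1r, the receptor of the incretin GLP-1, from 213 ± 15.4 to 96.8 ± 1.37 CPM (-1.14, SE 0.14, adjusted p = 0.0159). Of 24 genes of β-cell identity and maturity, 5 fell (Ucn3, Glp1r, G6pc2, Slc30a8 and Prlr), 19 did not pass and 0 rose. When adjusted over the list alone, 9 were lower. In the same libraries stromal (median 2.68), acinar (2.16) and immune (1.17) markers were higher as lists, with adjusted p = 0.250, adjusted p = 0.429 and adjusted p = 0.473 with an estimated correlation and the immune call lost without KO replicate 2 (0.433), and 5 immediate early and dissociation stress genes rose, and KO replicate 1 stood apart in Xist and Y-linked levels. Mafa (log2 fold change -0.82), Pdx1 (-0.52), Nkx6-1 (-0.35) and Slc2a2 (-0.00075), which encode transcription factors and the glucose transporter of β-cells, did not pass. Of 17 genes of hormone processing and the secretory granule, Vgf (-1.77), Chga (-1.02), Slc30a8 (-0.92) and Pcsk1 (-0.85) fell and 13 did not pass. Adjusted over the list alone, 11 were lower and 1 higher. Chga, a granule protein, went from 19948.2 ± 2529.53 to 9856.75 ± 128 CPM. Of 27 genes of exocytosis and calcium channels, 0 passed, also adjusted over the list alone, and Sytl4 (-1.06, adjusted p = 0.0845), Cplx1 (2.64) and Cacna1c (0.97) had the smallest p-values. The identity list was lower by camera (adjusted p = 2.21e-09; adjusted p = 0.250 with an estimated correlation), as was the granule list (adjusted p = 1.05e-06; adjusted p = 0.250 with an estimated correlation), and the exocytosis list was not (adjusted p = 0.169). Without heterozygous replicate 2, 0 identity and 0 granule genes passed (list medians -0.36 and -0.49), and without heterozygous replicate 1, 3 and 2 passed. As many as 8 granule genes passed without KO replicate 1 and 8 identity genes without KO replicate 2.

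**Figure D3:**
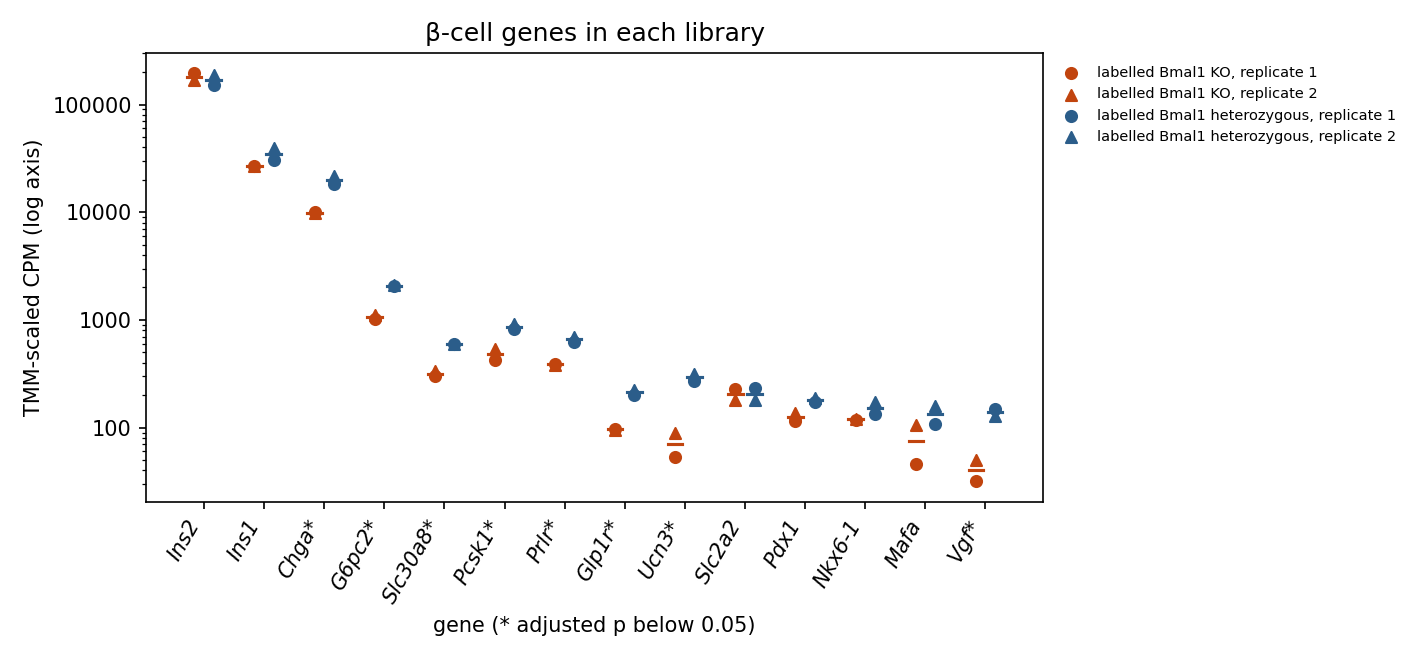
Level of 14 β-cell genes in each of the 4 libraries, in TMM-scaled CPM on a log axis; orange marks libraries labelled Bmal1 KO, blue those labelled heterozygous, and short lines are group means. Ins2 overlaps between the groups, while Ucn3 lies at 52.95 and 89.1 CPM in the libraries labelled KO and at 270 and 314 CPM in the others.

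Stress and signalling lists moved in part. Of 28 genes that are normally low in β-cells or rise on dedifferentiation, 2 rose, among them Serpina7 from 92.7 ± 17.0 to 466 ± 221 CPM (log2 fold change 2.33, SE 0.33, edgeR adjusted p = 0.0197), while 26 did not pass. Over the list alone, 9 were higher and 1 lower. In the same libraries stromal (median 2.68), acinar (2.16) and immune (1.17) markers had higher medians, the immune sum was high in KO replicate 2 alone, and KO replicate 1 stood apart in Xist and Y-linked levels. Of 29 immediate early and dissociation stress genes, Fos, Egr1, Ier2, Junb and Zfp36 rose, with log2 fold changes of 2.08, 1.69, 1.41, 1.20 and 1.06, and 24 did not pass. Of these 29, 7 were higher adjusted over the list alone. Fos was at 365 and 163 CPM in the libraries labelled KO against 54.0 and 71.3 CPM. Of 35 genes of ER stress and the unfolded protein response, Derl3 (-1.04), Pdia6 (-0.91) and Edem1 (-0.75), which fold or clear proteins of the ER, fell and 32 did not pass. Adjusted over the list alone, 10 were lower and 1 higher. Gpx3, a glutathione peroxidase gene, fell from 1470.6 ± 80.4 to 557 ± 122 CPM as the 1 of 27 antioxidant genes past the threshold, with 1 higher and 1 lower adjusted over the list alone. Gtse1 (-1.63), which is also a cell cycle gene, fell as the 1 of 30 p53 and apoptosis genes, with 2 higher and 1 lower adjusted over the list alone, and Rsad2 (-2.58) as the 1 of 38 interferon-stimulated genes, with 2 higher and 1 lower adjusted over the list alone. None of 22 NF-κB targets and cytokines passed in edgeR's test or adjusted over the list alone. Icam1 (2.51), Cxcl16 (0.96) and Nfkbia (0.90) had the smallest p-values. By camera the dedifferentiation list (adjusted p = 4.84e-06), the immediate early list (0.000110) and the NF-κB list (0.0459) were higher and the ER list lower (3.52e-07), with adjusted p = 0.277, adjusted p = 0.250, adjusted p = 0.421 and adjusted p = 0.320 with an estimated correlation, respectively. The antioxidant (0.688), p53 (0.123) and interferon (0.267) lists did not pass. Without heterozygous replicate 2, 0 immediate early and 0 ER genes passed and the NF-κB call was lost (0.405). Without heterozygous replicate 1, 1 immediate early gene passed. Without KO replicate 2, 8 immediate early and 9 ER genes passed, the NF-κB call was lost (0.187) and the interferon list was lower (0.0345).

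Of 22 glycolysis genes, 4 rose in the libraries labelled KO, 15 had a higher and 7 a lower level, and the median log2 fold change was 0.16, or 0.10 without KO replicate 1 and 0.31 without KO replicate 2. Pfkp, a phosphofructokinase gene, rose from 27.97 ± 5.14 to 106 ± 3.66 CPM (log2 fold change 1.92, SE 0.18, edgeR adjusted p = 0.0116), Pdk1, a kinase that restrains pyruvate dehydrogenase, from 36.0 ± 4.45 to 131 ± 43.1 CPM, Pfkfb3 from 30.2 ± 3.91 to 94.5 ± 23.6 CPM and Gpi1 from 107 ± 13.8 to 307 ± 125 CPM, while 18 did not pass. Over the list alone, 7 were higher. The stromal, acinar and immune markers and the dissociation stress genes given above for the β-cell genes differed in the same libraries. Low counts of Gapdh (10.4 ± 2.56 and 9.30 ± 0.0374 CPM) and Eno1 leave the counting behind this list in doubt. Of 23 cholesterol synthesis genes, 1 rose and 22 did not pass, with 1 higher adjusted over the list alone. None of 65 nuclear-encoded respiratory chain genes passed, also adjusted over the list alone, and Sdhd (0.64) and Atp5b (-0.36) had the smallest p-values. None of 76 ribosomal protein genes passed, also adjusted over the list alone, with Rps15a (-1.05), Rps14 (0.39) and Rpl4 (-0.31) nearest. Mitochondrially encoded mRNAs were absent from the table used (0 genes). By camera the glycolysis list (adjusted p = 4.31e-05; adjusted p = 0.250 with an estimated correlation) and the cholesterol list (adjusted p = 0.0317; adjusted p = 0.643 with an estimated correlation) were higher, and the respiratory (0.700) and ribosomal (0.584) lists did not pass. Without heterozygous replicate 2, 0 glycolysis genes passed and the respiratory list was higher (0.00274). Leaving out heterozygous replicate 1 instead, the respiratory list was lower (0.0374) and the cholesterol call was lost (0.211), and without KO replicate 1 the cholesterol call was lost (0.894).

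Markers of stromal cells were higher in the libraries labelled KO, and markers of other islet cells were not shifted as lists. Of 21 stromal and pericyte markers, 7 rose and 14 did not pass, with 17 higher adjusted over the list alone and a median log2 fold change of 2.68, also with Pdgfra at its bound. Col4a1, a basement membrane collagen gene, rose from 39.8 ± 4.21 to 274 ± 67.9 CPM, Fn1 from 0.613 ± 0.502 to 14.5 ± 6.78 CPM, Lum from 0.233 ± 0.184 to 4.81 ± 0.522 CPM and Col1a2 from 6.20 ± 2.56 to 48.7 ± 34.9 CPM. Pdgfra had 37 and 170 counts against 0 and 0, at least 38.2-fold higher when each heterozygous library is set to its floor of 3 counts. Of 26 immune markers, Fcer1g rose from 7.77 ± 0.154 to 22.0 ± 5.21 CPM and 25 did not pass, with 1 higher adjusted over the list alone. The list summed to 1444.52 and 4534.97 CPM in KO replicates 1 and 2 and to 1229.7 and 1307.43 CPM in heterozygous replicates 1 and 2. None of 27 acinar markers passed in edgeR's test or adjusted over the list alone although their median was 2.16, with Clps (2.92), Bhlha15 (-0.54) and Pnliprp1 (3.21) nearest. None of 8 endothelial markers passed (Pecam1 3.21, Plvap 2.54, Eng 1.96), and 2 were higher adjusted over the list alone. Dcdc2a, from 43.7 ± 14.5 to 348 ± 55.1 CPM, was the 1 duct marker of 15 that rose, with 3 higher and 1 lower adjusted over the list alone, and Tubb3 (0.99) the 1 of 10 neuronal and glial markers, with 1 higher adjusted over the list alone. Of 15 α-cell markers, Irx2 (2.64) rose, Gc (-0.92) and Tm4sf4 (-0.81) fell and 12 did not pass, with 3 higher and 4 lower adjusted over the list alone. Gcg was at 1629.51 and 3303.14 against 1340.09 and 1282.82 CPM (0.91, adjusted p = 0.183). None of 9 δ-cell markers passed, also adjusted over the list alone (Casr 0.42, Rbp4 0.44, Sst -0.035). Sst was at 539 and 1403 CPM in KO replicates 1 and 2 against 948 and 1043 CPM in heterozygous replicates 1 and 2. Of 6 PP-cell and ε-cell markers Sphkap (-0.97) fell and 5 did not pass, with 3 higher and 1 lower adjusted over the list alone. Ppy was at 1973.71 and 4007.95 against 1319.4 and 1046.24 CPM (1.34, adjusted p = 0.0850). The single erythroid gene measured, Bpgm (-0.69), did not pass in edgeR's test (adjusted p = 0.117), and a list of 1 gene allows no adjustment of its own.

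By camera the stromal (adjusted p = 1.64e-19), immune (4.31e-05), acinar (1.58e-06), duct (0.0103) and endothelial (0.0459) lists were higher, with adjusted p = 0.250, adjusted p = 0.473, adjusted p = 0.429, adjusted p = 0.473 and adjusted p = 0.414 with an estimated correlation, respectively. The α-cell (0.186), δ-cell (0.982), PP-cell (0.644) and neuronal (0.163) lists did not pass. Single libraries decided several of these calls. For the stromal list 2 genes passed without heterozygous replicate 2 and 14 without KO replicate 1. The immune call was lost without KO replicate 2 (0.433), the duct (0.603) and endothelial (0.283) calls without KO replicate 1, where the neuronal list was higher (0.00295), and the endothelial call without heterozygous replicate 1 (0.0666).

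**Figure D4:**
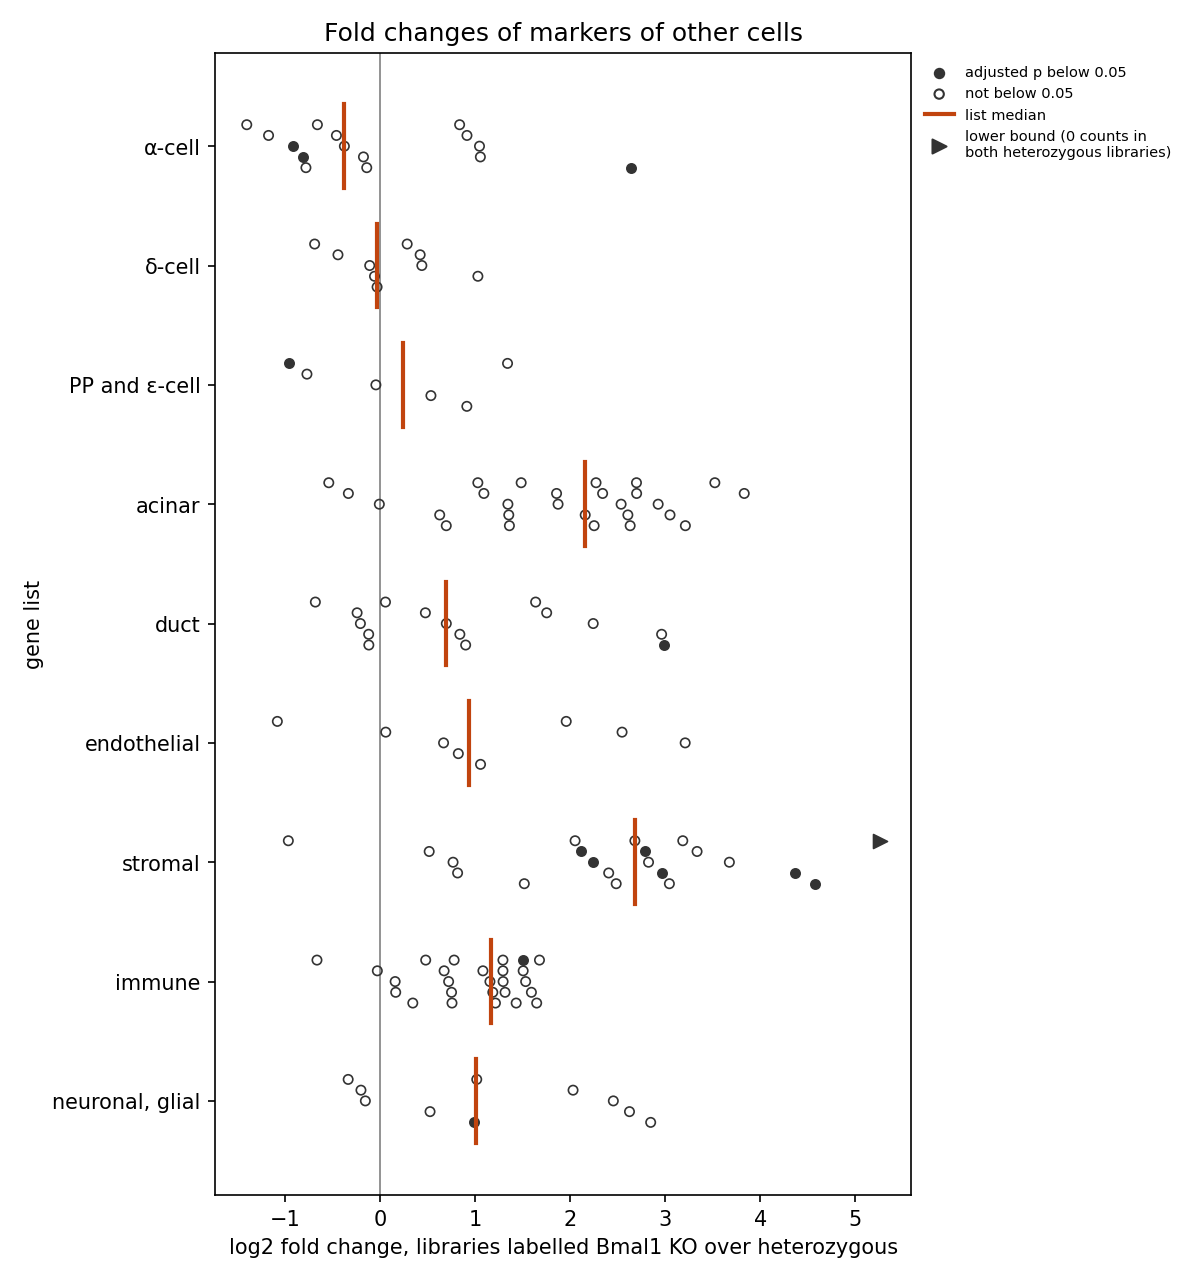
Log2 fold change (libraries labelled Bmal1 KO over heterozygous) of every measured marker of 9 other cell types; each point is a gene, filled where edgeR's adjusted p was below 0.05, the orange line is the list median, and the triangle is Pdgfra at its lower bound. The stromal list has a median of 2.68 and the δ-cell list a median of -0.035.

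Transcripts that differ by sex were present in every library and differed both between the labels and within the KO label. Xist, the X-inactivation RNA, was at 8.68 and 38.8 CPM in KO replicates 1 and 2 and at 72.3 and 67.5 CPM in heterozygous replicates 1 and 2. The Y-linked gene Ddx3y was at 89.1 and 23.8 CPM against 20.5 and 12.1 CPM, and Eif2s3y at 136 and 32.3 CPM against 36.9 and 20.2 CPM. Both libraries labelled KO lay below both labelled heterozygous for Xist and above both for Ddx3y, while Eif2s3y overlapped. Sex make-up may therefore differ with the label, and its part in the other differences was not tested. None of the 6 genes of this list passed in edgeR's test or adjusted over the list alone, and camera's adjusted p was 0.482. With the replicate block in the fit, camera's adjusted p was 0.0482 and the list passed as higher. The list joins Xist and Tsix with Y-linked genes, and 4 members lay above 0 and 2 below. Camera asks whether a list moves 1 way, so neither value can decide whether sex make-up differed. Of the 29 lists tested by camera with a preset correlation, 12 were higher, 6 lower and 11 did not pass. With an estimated correlation 0 passed. In simulated data the estimated setting found a planted 2-fold list in 0 of 5 sets and the preset one in 5 of 5. Genes were simulated independently of each other, so this does not show which setting is right for lists whose genes vary together. A list that did not pass with an estimated correlation is not thereby shown to be unchanged.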

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

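The tests without markers of other cells and on recovered reads were chosen after the result was seen. The main counts were 176 genes higher and 196 lower in the libraries labelled KO. No filter gave 430 and 378, DESeq2 619 and 560, adjusted p below 0.1 378 and 350, and a test against a fold of 1.5 81 and 75, where the last pair of settings differ by construction. For no filter and DESeq2 the cause was not tested. A mean CPM of 5 or more gave 266 higher. Leaving out 1 library gave 17 to 404 higher and 8 to 422 lower, with the lowest counts without heterozygous replicate 2, where 16 and 7 of the genes were shared with the main test, and the Arntl log2 fold change ranged from 1.61 to 2.23, past the threshold except without heterozygous replicate 2 (adjusted p = 0.0724, against 2.33e-10 to 0.0366 under the other alternatives). Lists passing numbered 18 with camera's preset correlation, 0 with an estimated correlation and 1 by fry. They were 16 to 17 with 1 library left out, 13 under limma-voom, 13 without markers of other cells, where 6 lists were taken out, 14 with a mean CPM of 5 or more, where 2 lists had too few members, 15 under limma-trend, and 16 with library sizes only and with no filter. Estimated correlation and fry aside, the lists lost in at least 1 planned fit were the E-box, REV-ERB, NF-κB, duct, endothelial, immune and cholesterol lists. Recovered reads gave the same 176 and 196 genes, and leaving out markers of other cells gave 186 and 208. Among scalings, library sizes only moved the share of higher calls from 47.3% to 53.1%, and no scaling moved the median of all genes by over 0.046. The labels do not say whether replicate numbers pair libraries across the groups. The correlation across genes of deviations from group means was -0.0189, which does not exclude a pairing that acts on some genes. The replicate block gave 313 higher and 278 lower genes and 16 lists, among them the sex-linked list. Over named genes and alternatives, 1875 results kept their side of the threshold, 59 gained the threshold and 129 lost it. Among the 1875, a gene called in neither fit could change sign if it moved by at most 1 standard error. In 3 results without a call the sign changed by more than that, and 0 called genes reversed.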

Other observations

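The Reactome sets, the single genes and the tests of explanations in this part were chosen after the values were seen. Of 859 Reactome sets, 31 were higher and 105 lower by camera with a preset correlation, and 0 passed with an estimated correlation. Sets of extracellular matrix, which share Col1a2, Col4a1 and Col6a1 with the stromal list and in part repeat it, were higher, such as assembly of collagen fibrils (32 genes, 5 higher and 1 lower in edgeR's test, adjusted p = 9.96e-08; adjusted p = 0.856 with an estimated correlation) and laminin interactions (24 genes, 3 higher, adjusted p = 2.68e-05; adjusted p = 0.856 with an estimated correlation). Col4a1, Col4a2, Col6a1, Col18a1 and Col1a2 rose, while Col16a1 (log2 fold change -1.75) and Col27a1 (-2.06) fell. Sets of N-glycan trimming in the ER were lower (13 genes, 1 past the threshold, adjusted p = 0.000213; adjusted p = 0.856 with an estimated correlation).

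Single genes picked after their values were seen follow, and they stand for no group: the Reactome sets of PPARα-regulated lipid metabolism (18 genes, 1 higher, adjusted p = 0.774) and of fatty acid, triacylglycerol and ketone body metabolism (83 genes, 4 higher and 1 lower, adjusted p = 0.469) did not pass. Ppara, a fatty acid sensor, was at 14.4 ± 8.77 against 0.881 ± 0.296 CPM, Pdk4 at 10.3 ± 2.39 against 1.23 ± 0.118 CPM, Lpl at 143 ± 25.9 against 29.0 ± 7.17 CPM, Plin2 at 89.1 ± 23.7 against 22.0 ± 2.40 CPM and Cpt1a at 96.4 ± 1.05 against 45.8 ± 0.386 CPM (n = 2 per group). The glucagon receptor gene Gcgr rose from 140 ± 28.7 to 458 ± 107 CPM. Il22, a cytokine gene, and its near-identical copy Iltifb had 173 and 138, and 121 and 69, counts in the libraries labelled KO and 0 in both heterozygous libraries, at least 56.9-fold and 34.7-fold higher at a floor of 3 counts per library. Kcnj3, a potassium channel gene, had 107 and 89 counts against 0 and 0.

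Spc25, a kinetochore gene, stood at 682 ± 36.4 CPM in the heterozygous libraries, while its partners Nuf2 and Spc24 stood at 23.1 ± 4.09 and 25.5 ± 3.53 CPM; it ends 4878 bases from G6pc2 on chromosome 2. Gapdh was at 10.4 ± 2.56 and 9.30 ± 0.0374 CPM and Eno1 at 0.555 ± 0.00992 and 0.802 ± 0.107 CPM in the libraries labelled KO and heterozygous. These low counts of abundant glycolysis genes, and the high count of Spc25, put in doubt how reads were assigned, and with it the glycolysis and ribosomal lists and Spc25 itself. Within 10 Mb of Arntl and without it, 4 of 122 tested genes passed (3.28%, against 2.54% of all genes).

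Arntl was higher in the libraries labelled KO, and an exchange of the labels between groups would need genes driven through E-boxes to be higher as a set. Camera gave this for that list (adjusted p = 0.0284; adjusted p = 0.421 with an estimated correlation) and for a Reactome set of BMAL1 targets that holds Arntl itself (14 genes, 6 higher and 0 lower, adjusted p = 9.96e-08; adjusted p = 0.856 with an estimated correlation), while Nr1d2 and Per3 fell, the list's quartiles were -0.54 to 1.01 and its median of 0.44 went to 0.0014 without KO replicate 2, so an exchange cannot be told apart from correct labels on these counts. Collection at another time of day, which the labels do not give, would move Nr1d1, Nr1d2, Per1, Per2, Per3, Dbp and Tef together; their median was -0.96, but Per1 and Per2 lay above 0 within 2 standard errors, so it stays open. A candidate biological explanation is that less REV-ERB lifts repression of Arntl in cells without functional BMAL1, as Npas2 and Nfil3 rose, but the REV-ERB list (median 0.75, quartiles -0.15 to 1.69) held members on both sides, and its median ranged from 0.087 without KO replicate 2 to 1.57 without heterozygous replicate 2, so it does not decide it. Reads over single exons of Arntl, not analysed here, would test an exchange of labels alone.

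Mitosis genes were lower in the libraries labelled KO. A lower share of β-cells does not account for it, since β-cell identity genes had a median of -0.37 (quartiles -0.93 to -0.088) where the mitosis list had quartiles of -2.49 to -2.23. More immune, stromal, endothelial or acinar cells in the heterozygous libraries would make their markers lower in the libraries labelled KO. All 4 lists lay above 0 (lowest median 0.94), which argues against that. Markers measure the amount of such cells and not their division, so fewer but cycling cells of these kinds in the heterozygous libraries are not excluded. A factor per library moves every gene alike, so scaling does not account for the lower mitosis genes either. The mitosis list median lay -2.40 from that of all other genes, whose quartiles were -0.23 and 0.39. Fewer dividing β-cells in the libraries labelled KO may be the reason, as a hypothesis that counts of β-cells stained for MKI67 would test; dividing cells of α, duct or other kinds, sex make-up and the extent of ablation were not tested.

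Stromal markers were higher in the libraries labelled KO. A lower share of β-cells would raise the markers of every other type alike. The δ-cell list had a median of -0.035 (quartiles -0.11 to 0.42) and the α-cell list of -0.38 (-0.80 to 0.87) against stromal quartiles of 2.05 to 3.18. These lists cannot settle it. Members such as Tm4sf4 (741 CPM) and Gc (399 CPM) were abundant in the heterozygous libraries and may come from β-cells. Of the hormone genes, Gcg (0.91) and Ppy (1.34) were higher in both libraries labelled KO, though neither passed. Sst (-0.035) was below both heterozygous libraries in KO replicate 1 (539 CPM) and above both in KO replicate 2 (1403 CPM), so its value averages opposite shifts. The log2 fold changes of Gcg, Ppy and Sst lay below the stromal quartiles, so a lower share of β-cells alone does not account for the stromal rise. A part in it is not excluded, as acinar (2.16), immune (1.17), endothelial (0.94) and duct (0.69) medians lay above 0 too. RNA from 1 kind of stromal cell, which the sort should remove, could be the source if the markers kept 1 ratio between the libraries labelled KO; the log2 ratios of 19 markers had an interquartile range of 1.41 and a full range from -1.25 (Tagln) to 2.37 (Postn). Of 3 references tried, counting error (16 of 19 markers outside) is no evidence because the libraries differ beyond it in general, all genes in the same range of counts (0.562) spoke against it, and the closest, 887 genes nearest in counts (0.707, or 1.41 when doubled, the limit set), did not quite, so a single source cannot be told apart from several or from expression by β-cells themselves. Among the abundant markers, Col4a1 was at 322 and 226 CPM and Col1a2 at 24.0 and 73.3 CPM in KO replicates 1 and 2.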
